A study of Homo sapiens with 80 samples.

How the data were processed

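Ribosomal-RNA-depleted, strand-specific total RNA was sequenced from H9 human embryonic stem cells, an established pluripotent line, in 80 libraries of 2 sets. Per the labels' protocols, cells on Matrigel in mTeSR medium received a bisphenol in 0.1% DMSO every day for 3 days, were lysed 24 hours after the last dose in TRIzol or QIAzol, and 6 wells were pooled per replicate. The high-concentration set has 44 libraries (12 treated groups of 3 and 8 controls) and the low-concentration set 36 (8 treated groups of 3 and 12 controls). Replicates are separate samples per the labels, which do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

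Per the layout of the deposited files, each holds raw read counts per Ensembl gene in 3 strand settings, after 4 summary lines. The aligner, its version, the genome build and the annotation release are not given in the sources used here. The reverse-strand counts were used, since they held most gene reads. The 4 summary lines (unmapped, multimapped, no feature, ambiguous) stayed out of library sizes and tests; reads in them made up 33.2 to 50.4% (median 36.3%) of the high set and 39.9 to 74.0% (median 42.4%) of the low set. Of 58302 gene IDs, 58039 took a symbol and position from GENCODE release 29. Unique counting leaves uncertain the levels of genes that share sequence with copies, among them POU5F1, ribosomal protein, metallothionein, histone, heat shock and mitochondrial genes.

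Reads on genes, in units of 1e6, ranged from 14.7 to 33.1 per library in the high set (median 23.7) and from 8.27 to 22.3 in the low set (median 18.2). A chi-square comparison found 7 pairs of controls, each of 1 run, whose counts differed by little more than sampling noise (ratio to its expectation 1.02 to 1.05, p from 6.39e-06 to 0.0283, against at least 1.72 for any other pair of a group). Pairs with a ratio under 1.1 were each counted as 1 sample, by their summed counts, which left 7 controls in the high set and 6 in the low set.

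Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM normalization, glmQLFit with robust settings and the quasi-likelihood F test, 1 fit per set over all its groups. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05 over the 19561 genes kept in the high set or the 17876 in the low set; the number that also changed at least 2-fold is given beside. Fold changes are log2 values with standard errors (SE), levels are CPM with the SD over libraries. On simulated counts for BPA at 250 µM (18427 genes), 46 of 67 genes changed 1.5-fold and all 67 changed 2-fold were recovered, with 3.76% false calls. For BPA at 10 µM (17584 genes) it was 65 of 67 and 66 of 67, with 4.83% false. The simulations do not measure calls that come from differences between runs, so these shares of false calls need not hold for the data.

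Named genes were chosen by a rule set before the data were examined, as were the design, the lists and 17 alternatives. They are protein-coding, pass the test, reach a mean of 1 CPM in either group and have every library of a group beyond every library of the other. The 12 largest changes each way were taken at each compound's highest concentration, 4 each way at 1 and 10 µM and 5 each way between groups. POU5F1, NANOG, SOX2, ESR1, ESR2, ESRRA and ESRRG were always included, and up to 4 members per list. A gene with 0 reads in a group was set against a floor of 3 reads over the group, and 1 to 3 reads gave a ratio with a 95% interval; both cover counting error only.

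The 46 gene lists hold 1037 genes and cover pluripotency, germ layers and other cell types, nuclear receptors and hormones, lipid, mitochondrial and stress pathways, cell cycle and chromatin. HOX genes had under 3 measured members, which left 45 lists. Each was tested with camera at a preset correlation of 0.01, adjusted over lists; camera with an estimated correlation is given beside. A list's mean log2 CPM was compared with limma 3.58.1 (prior count 2), which gives the differences with 95% intervals. Counts "adjusted over the list alone" repeat the adjustment within the list.

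Title numbers run in sequence, and each control number was taken to open a run that holds the treated libraries numbered after it. The labels do not state this, and every own-run value rests on it. The 2 libraries of the TBBPA run's control are titled with BPA and CP, and the numbers of 400 µM BPF do not directly follow those of its control. In the high set, BPA, BPS and TBBPA each lie in 1 run and the 3 BPF concentrations in 3, so compound and run can be told apart only through the controls. Own-run values compare each group with its own control, with the spread pooled over the set; between runs they are differences of such differences. In the low set each run holds a control and 1 replicate of each of 4 groups. Of 60 same-run pairs, 47 had correlated deviations from their group means (r above 0.1, median 0.19). Every pair did so for BPA and BPF at 10 µM and BPS at 1 and 10 µM, so for these the fit with the run as a block is printed beside. Below, the run is said to pair libraries only where this held, although all low-set groups share their runs with controls.

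Benchmark concentrations used 17625 genes in both sets, as log2 CPM minus the mean of the set's controls. Genes that passed a limma F test and changed at least 2-fold were fitted with linear, power and Hill curves (exponents 1 to 18). The best gave the concentration at which it left the control mean by 1 SD of the controls, with 95% intervals from 100 resamplings of libraries. On simulated genes for BPS with noise of that SD, true values of 5, 50, 200 and 350 µM gave medians of 5.0, 50.0, 200.1 and 328.5 µM, with 39, 34, 47 and 45 of 50 genes within 2-fold. DESeq2 1.42.0 was among the alternatives. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 gave the curve fits, exact permutation tests and figures.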

Results

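Transcript levels were measured in H9 human embryonic stem cells exposed for 3 days to bisphenol A (BPA), bisphenol F (BPF), bisphenol S (BPS) or tetrabromobisphenol A (TBBPA, labelled TBBA). The series title names the question, the relative potency of the 4 compounds by benchmark dose. All are pairs of phenol rings joined by a bridge: BPF has a methylene bridge where BPA has an isopropylidene bridge, BPS has a sulfonyl bridge, and TBBPA is BPA with 4 bromine atoms on its rings. In the high-concentration set, 3 libraries each were made at 200, 225 and 250 µM BPA, at 250, 375 and 400 µM BPF, at 300, 400 and 500 µM BPS and at 500, 650 and 700 µM TBBPA. In the low-concentration set, each compound was given at 1 and 10 µM, again in 3 libraries each. The vehicle controls numbered 7 and 6 after 7 pairs were each counted as 1 sample, as described above. Each set was compared with its own controls.

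The number of genes that differed from the vehicle controls rose with concentration for each compound in the high set. BPA changed 1940, 4650 and 6086 of 19561 genes at its 3 concentrations, BPF 6317, 9536 and 10116, BPS 6996, 10470 and 12782, and TBBPA 460, 5636 and 15355. Changes of at least 2-fold numbered 1268 at 250 µM BPA, 2877 at 400 µM BPF, 5430 at 500 µM BPS and 9592 at 700 µM TBBPA. In the low set, 14 genes or fewer changed with BPA, 3 or fewer with BPF, 31 or fewer with BPS and 4 or fewer with TBBPA in the fit without the run, and none of them reached a 2-fold change. With the run as a block, 105 changed at 10 µM BPA, 28 at 10 µM BPF and 65 and 52 at 1 and 10 µM BPS. In these comparisons the deviations of same-run libraries correlated in every run. The other comparisons share runs with controls too. There the block also called more genes, by far the most at 1 µM BPA, as given below. Against the single control of their own run, the counts in the high set were 660, 872 and 1484 for BPA, 675, 3713 and 4355 for BPF, 3775, 6076 and 8578 for BPS, and 2284 and 13434 for TBBPA at 650 and 700 µM. At 500 µM TBBPA 174 of the 460 genes were called with both kinds of control, and other splits of those libraries gave as many genes too often to exclude chance. At least 96.8% of the genes called against all controls had the same sign against the own-run control. This share, like those between groups below, says little. Both comparisons use the same treated libraries, the own-run control is among all controls, and a shrunken value can keep its sign.

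**Figure D1:**
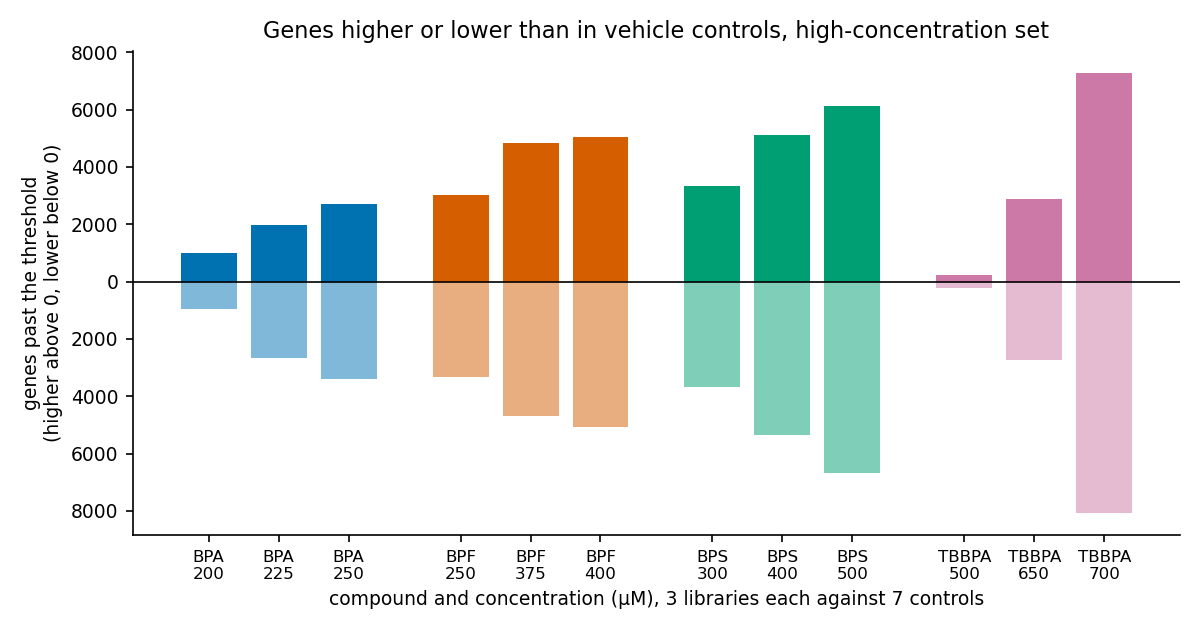
Number of genes higher (above 0) or lower (below 0) than in the vehicle controls in the high set (edgeR, adjusted p under 0.05), 1 bar per compound and concentration in µM, 3 libraries each against 7 controls. In all, 1940 genes changed at 200 µM BPA and 460 at 500 µM TBBPA.

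BPA at 250 µM lowered genes of glycolysis and the hypoxia response, genes of the actin cytoskeleton and YAP signalling, and genes of retinoic acid metabolism, 3 lists that were not called with an estimated correlation. The receptor genes UNC5C and TLR4 and the ERK phosphatase gene DUSP6 rose. Of 33 measured hypoxia and glycolysis genes, 30 fell, 0 rose and 3 did not pass (32 fell adjusted over the list alone). Their mean log2 difference was -0.82 (95% interval -1.01 to -0.63, n = 3 against 7; own-run -0.86), with a camera adjusted p of 3.24e-21 and an adjusted p = 0.0634 with an estimated correlation. Among them, the glycolytic enzymes ENO2, PKM and ALDOA fell by 1.13 (SE 0.10), 1.09 (SE 0.12) and 1.07 (SE 0.12). Of 26 cytoskeletal and YAP genes, 20 fell and 6 did not pass, also adjusted over the list alone. Their mean was -0.61 (-0.75 to -0.47; own-run -0.43), camera adjusted p 1.32e-10 and adjusted p = 0.0634 with an estimated correlation. TPM1, a tropomyosin that stabilizes actin filaments, fell by 1.49 (SE 0.08). In the retinoic acid list 5 genes fell, 2 rose and 8 did not pass, also adjusted over the list alone (camera adjusted p 0.0127, adjusted p = 0.512 with an estimated correlation). Its members CYP26A1, which degrades retinoic acid, and CRABP2, which binds it, fell by 3.65 (SE 0.47) and 1.68 (SE 0.18).

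The largest rise at 250 µM BPA was in TLR4, a receptor for bacterial lipopolysaccharide (ENSG00000136869, chromosome 9, positions 117704175 to 117724730 of GENCODE 29 on GRCh38). Its level was 5.07 ± 0.725 CPM against 0.331 ± 0.133 CPM (log2 3.89, SE 0.25, adjusted p 1.91e-15). The netrin receptor UNC5C rose by 3.00 (SE 0.15), the adhesion receptor ADGRL4 by 2.65 (SE 0.18) and DUSP6 by 2.08 (SE 0.13), from 118 ± 32.6 to 499 ± 77.4 CPM. The homeobox genes SIX6, GBX2 and HMX2, the regulators LMO3 and NPAS3, and LPAR6, RIMBP2 and TLL1 made up the 12 largest increases, the smallest of them 2.02. Rankings here and for the other compounds hold among the genes that met the rule for named genes. Among them, decreases were led by NDUFA4L2, a hypoxia-induced mitochondrial protein, at -4.35 (SE 0.39). The neuronal pentraxin NPTX1 was at -4.16 (SE 0.31, 2.30 ± 0.438 against 40.9 ± 15.2 CPM) and myoglobin (MB) at -4.00 (SE 0.67). The germ-cell gene DAZL, the neural regulator SOX21 and the scaffold protein AHNAK fell by 3.45, 3.08 and 3.20, and FAM20A, ALPG, HTR1D, SCNN1G and IRX2-DT were also among the 12 largest. By camera 6 other lists were called. In the integrated stress response list 13 rose and 3 fell, led by ALDH1L2 at 1.35 and the serine-synthesis enzyme PSAT1 at 1.15 (adjusted p = 0.621 with an estimated correlation). Of 13 genes of the mitochondrial genome 8 rose and 1 fell (11 and 1 adjusted over the list alone), adjusted p = 0.621 with an estimated correlation. Among neurodevelopmental genes 7 rose and 2 fell (estimated-correlation adjusted p = 0.512). Among immediate-early genes 9 rose and 2 fell (p = 0.621), among p53 targets 10 rose and 2 fell (p = 0.740) and of 42 ribosomal protein genes 17 fell (p = 0.796). At 200 µM BPA, 14 cytoskeletal genes fell, with TPM1 at -1.30 (SE 0.08), and 12 p53 targets rose, with BTG2 at 0.94 (SE 0.15). Those lists had adjusted p = 0.0506 and 0.291 with an estimated correlation. The count at 200 µM was 1128 without its replicate 3, and the count at 225 µM was 2241 without its replicate 3.

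BPF at 400 µM raised immediate-early genes, which transcribe within minutes of a stimulus, and enzymes of cholesterol and fatty acid synthesis, and lowered genes of mitosis and ribosomal proteins. The last 2 lists were not called with an estimated correlation (adjusted p = 0.107 and 0.407). Of 30 immediate-early genes, 28 rose, 1 fell and 1 did not pass (28 and 2 adjusted over the list alone). Their mean was 1.83 (95% interval 1.62 to 2.04, n = 3 against 7; own-run 1.84), camera adjusted p 7.73e-32 and adjusted p = 0.00171 with an estimated correlation. EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) was at 117 ± 58.7 CPM against 5.24 ± 2.03 CPM (log2 4.47, SE 0.28, adjusted p 1.51e-14), and FOS, FOSB and JUNB rose by 3.29, 3.08 and 2.80. Of 26 cholesterol synthesis genes 24 rose and 1 fell, also adjusted over the list alone, with a mean of 1.17 (1.01 to 1.34; own-run 1.24) and adjusted p = 0.0061 with an estimated correlation. INSIG1, the sterol sensor that restrains SREBP processing, rose by 2.26 (SE 0.10). Of 14 fatty acid synthesis genes 12 rose and 2 did not pass, also adjusted over the list alone, with a mean of 1.11 (0.98 to 1.24) and adjusted p = 0.00161 with an estimated correlation. The desaturases FADS1 and SCD rose by 1.11 (SE 0.06) and 1.38 (SE 0.10). Of 32 mitosis genes 27 fell (28 adjusted over the list alone), with KIF20A at -1.30 (SE 0.12) and CCNB2 at -1.15 (SE 0.10). The list had adjusted p = 0.107 with an estimated correlation.

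NOG, a secreted BMP antagonist, rose most at 400 µM BPF, from 0.574 ± 0.158 to 21.7 ± 7.68 CPM (log2 5.24, SE 0.22, adjusted p 3.19e-21). The Notch ligand DLL4 rose by 4.99 (SE 0.36), the Notch target HEY1 by 3.88 (SE 0.22), MXD1, which opposes MYC, by 3.98 (SE 0.24), and ANKRD37, a hypoxia-induced gene, by 3.58 (SE 0.23). EGR4, EGR3, NR4A3, APOLD1, DUOX2 and DLX2 completed the 12 largest increases. DAZL fell by 3.83 (SE 0.35), INHBA by 3.45 (SE 0.49), the phospholipase-C-like gene PLCL2 by 2.91 (SE 0.20), AHNAK by 2.85 (SE 0.31) and TXNIP, a glucose-responsive inhibitor of thioredoxin, by 2.79 (SE 0.20). C11orf86, RDH8, SGMS2, TNNT2, MAP1LC3C, KLK6 and HTR1D were the others. Neurodevelopmental genes (21 rose, 0 fell; adjusted p = 0.107 with an estimated correlation), the integrated stress response (25 rose, 2 fell; p = 0.214), calcium and ion channels (13 rose, 2 fell; p = 0.167) and TGF-beta, NODAL and BMP targets (12 rose, 4 fell; p = 0.107) were higher by camera. So were neural crest genes (7 rose, 1 fell; p = 0.107), cell-cycle inhibitors (10 rose, 2 fell; p = 0.256), ER chaperones (12 rose, 4 fell; p = 0.407) and estrogen-responsive genes (11 rose, 3 fell; p = 0.214). The estrogen-responsive members were led by EGR3 at 3.56, an immediate-early factor, and the retinoic acid receptor RARA at 1.06. Ribosomal proteins (37 fell, 0 rose; p = 0.407), nuclear-encoded oxidative phosphorylation genes (30 fell, 0 rose; p = 0.462) and p53 targets (19 fell, 7 rose; p = 0.583) were lower. Against the own-run control the means of these last 2 lists were -0.25 (-0.54 to 0.05) and -0.15 (-0.35 to 0.04).

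Hypoxia and glycolysis genes did not follow concentration with BPF. At 375 µM all 33 fell, with a mean of -1.64 (-1.84 to -1.45; own-run -1.56) and adjusted p = 0.00673 with an estimated correlation. At 400 µM 10 rose, 14 fell and 9 did not pass, with a mean of 0.06 (-0.13 to 0.26). The enzyme ENO2 fell by 2.17 (SE 0.11) and the collagen hydroxylase P4HA2 by 2.45 (SE 0.14) at 375 µM. At the same concentration 18 of 26 cytoskeletal and YAP genes fell and 1 rose, with a mean of -1.05 (-1.19 to -0.91; adjusted p = 0.0157 with an estimated correlation), and the YAP target CCN2, a matrix-associated growth factor, fell by 3.39 (SE 0.21). Fibroblast and stroma markers, several of them also cytoskeletal, fell in 9 of 12 cases and rose in 1, with adjusted p = 0.0404. At 250 µM BPF, 15 of 25 pluripotency genes rose and 5 fell, with a mean of 0.55 (0.38 to 0.72), and neuroectoderm genes fell in 10 cases and rose in 1, with a mean of -0.56 (-0.82 to -0.31). Both lists had adjusted p = 0.204 with an estimated correlation. Their own-run means were 0.26 and -0.02, and the controls of the runs that hold 250 and 375 µM BPF differed from the other 5 controls in 2404 genes.

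BPS at 500 µM raised genes of early forebrain and eye development, neural crest, cholesterol and fatty acid synthesis and the integrated stress response, and lowered genes of glycolysis and mitosis. The integrated stress response and mitosis lists were not called with an estimated correlation (adjusted p = 0.0946 and 0.218). Of 25 neuroectoderm genes 20 rose, 1 fell and 4 did not pass (20 and 2 adjusted over the list alone). Their mean was 2.59 (95% interval 2.33 to 2.84, n = 3 against 7; own-run 2.33), camera adjusted p 1.13e-16 and adjusted p = 0.000505 with an estimated correlation. The LIM homeobox gene LHX2 (ENSG00000106689, chromosome 9, 124001670 to 124033301) was at 18.5 ± 1.65 CPM against 0.191 ± 0.140 CPM (log2 6.48, SE 0.24, adjusted p 1.80e-23). SIX6 rose by 6.02 (SE 0.25), ZIC1 by 4.40 (SE 0.22) and RAX, a regulator of eye-field formation, by 3.78 (SE 0.22). Of 13 neural crest genes 9 rose and 1 fell, also adjusted over the list alone, with a 95% interval of the mean of 1.25 to 1.56 and adjusted p = 0.00635 with an estimated correlation. CDH6 rose by 4.73 (SE 0.19) and SOX9 by 2.53 (SE 0.19). Of 26 cholesterol synthesis genes 25 rose and 1 fell, also adjusted over the list alone, with a mean of 1.29 (1.12 to 1.45; own-run 1.37) and adjusted p = 0.0227 with an estimated correlation. Fatty acid synthesis genes rose in 13 of 14 cases and fell in 1 (interval of the mean 1.07 to 1.32; adjusted p = 0.00635), with SREBF1, the transcription factor that drives this pathway, at 2.95 (SE 0.18). Of 33 hypoxia and glycolysis genes 31 fell and 1 rose (32 and 1 adjusted over the list alone), with a mean of -1.59 (-1.78 to -1.40; own-run -1.56) and adjusted p = 0.0386 with an estimated correlation. LDHA, which makes lactate, fell by 3.52 (SE 0.19) and P4HA2 by 3.48 (SE 0.15).

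The Notch ligand DLL4 rose from 0.126 ± 0.0725 to 13.9 ± 0.691 CPM at 500 µM BPS (log2 6.80, SE 0.31). UNC5C rose by 5.53 (SE 0.14), TLR4 by 5.46 (SE 0.23), MECOM by 5.79 (SE 0.24), DLX2 by 5.44 (SE 0.28) and SIX3 by 5.40 (SE 0.38), and CNTN6, ZBTB16 and RNF151 were also among the largest. INSM2, with 3 reads in the controls, was 107-fold higher (counting interval 35.5 to 530). CD300A, an inhibitory immune receptor, had 1 read in the treated libraries and was 279-fold lower (49.9 to 11000). RDH8, NCR1, PRR15L, MYCT1 and KLK6 were also left with 1 or 2 reads. The peptide ligand APLN fell by 5.23 (SE 0.44), the cytidine deaminase APOBEC3B by 5.04 (SE 0.31), ANKRD33 by 4.95 (SE 0.33), PDGFB by 4.78 (SE 0.50) and GABRP by 4.77 (SE 0.30). The endothelin receptor EDNRB fell by 4.92 (SE 0.77) against all controls and by 2.94 against the own-run control. The integrated stress response rose in 30 of 34 genes and fell in 2 (mean 1.25, own-run 1.41; adjusted p = 0.0946 with an estimated correlation), with asparagine synthetase ASNS at 2.45 (SE 0.14). Imprinted genes (11 rose, 2 fell; adjusted p = 0.00459) and TGF-beta, NODAL and BMP targets (19 rose, 2 fell; p = 0.0170) were called with an estimated correlation too, with CDKN1C at 1.91 and the BMP antagonist GREM1 at 3.99. Immediate-early genes (23 rose, 2 fell; p = 0.0771), cell-cycle inhibitors (8 rose, 4 fell; p = 0.179), neurodevelopmental genes (18 rose, 5 fell; p = 0.474), DNA replication genes (21 rose, 3 fell; p = 0.423) and ER chaperones (15 rose, 4 fell; p = 0.269) were higher by camera. Mitosis genes (29 fell, 1 rose; p = 0.218), ribosomal proteins (37 fell; p = 0.572), oxidative phosphorylation (31 fell; p = 0.573), cytoskeletal genes (11 fell, 3 rose; p = 0.534) and fat oxidation (9 fell; p = 0.423) were lower. At 300 µM BPS all 33 hypoxia and glycolysis genes fell (mean -1.38; own-run -1.35; adjusted p = 0.00263) and 21 of 33 p53 targets fell, with DDB2, which recognizes UV damage, at -1.98 (SE 0.13; list p = 0.215).

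TBBPA at 500 µM raised genes of the integrated stress response and metallothioneins, and at 700 µM it changed 15355 of the 19561 genes. Where most genes changed, as there and at 500 µM BPS, rises and falls are relative to the scaling. TMM takes most genes as unchanged, and RNA amounts per cell were not measured. Of 34 integrated stress response genes, 21 rose at 500 µM (26 adjusted over the list alone), 32 at 650 µM and 32 at 700 µM, where 2 fell. The means were 0.62 (95% interval 0.41 to 0.84), 1.70 (1.48 to 1.91) and 2.17 (1.95 to 2.38), with own-run 0.64, 1.71 and 2.18. With an estimated correlation the adjusted p = 0.00219, 5.55e-06 and 0.0957. DDIT3, a transcription factor of this response (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose by 1.53 (SE 0.16), 3.24 (SE 0.15) and 4.14 (SE 0.15). At 500 µM, 5 of 10 metallothionein-list genes rose (8 adjusted over the list alone; mean 0.65, 0.37 to 0.93; own-run 0.79; adjusted p = 0.0158 with an estimated correlation). MT2A, which binds zinc and copper, was at 0.88 (SE 0.16) and the zinc exporter SLC30A1 at 0.97 (SE 0.14). At 650 µM none of the 10 rose and 2 fell (mean -0.07, -0.36 to 0.21; own-run 0.07), and at 700 µM 5 rose and 3 fell (mean 0.60; own-run 0.74), and the list was not called at either. At 650 µM, oxidative stress genes rose in 14 of 28 cases (adjusted p = 0.00924), with heme oxygenase HMOX1 at 4.28 (SE 0.32), and ER chaperones rose in 12 of 23 cases (adjusted p = 0.0229), with HSPA5 at 1.53 (SE 0.12). At 650 µM, 30 hypoxia and glycolysis genes fell and 1 rose (mean -0.86; adjusted p = 0.0253), and 20 of 30 immediate-early genes rose (mean 0.73; adjusted p = 0.0229). Against the own-run control these last 4 lists kept their direction and were not called with an estimated correlation (adjusted p = 0.0857 for hypoxia and 0.0989 for the other 3).

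At 700 µM TBBPA, 27 of 30 immediate-early genes rose and 2 fell (mean 2.41, 2.20 to 2.62; own-run 2.34), with FOSB at 5.51 (SE 0.18) and the phosphatase DUSP1 at 4.15 (SE 0.13). Of 42 nuclear-encoded oxidative phosphorylation genes 40 fell and 2 rose (mean -1.45; own-run -1.53), and of 42 ribosomal protein genes 41 fell (mean -1.24). Of 32 mitosis genes 28 fell and 3 rose (mean -1.28), with the mitotic kinase CDK1 at -3.10 (SE 0.17), and 27 of 33 hypoxia and glycolysis genes fell and 3 rose (mean -1.48), with LDHA at -4.20 (SE 0.20). PGK1, another glycolytic enzyme, was at 103 ± 27.6 CPM against 1997 ± 203 CPM (log2 -4.28, SE 0.23, adjusted p 1.92e-19). Cell-cycle inhibitors (11 rose, 3 fell; mean 1.88) included GADD45G at 5.35 (SE 0.22), and neural crest genes (10 rose, 1 fell; mean 1.58) included TWIST1 at 4.19 (SE 0.31). None of these lists was called at 700 µM with an estimated correlation, where adjusted p = 0.0957 for immediate-early genes, 0.613 for oxidative phosphorylation, 0.716 for ribosomal proteins, 0.472 for mitosis, 0.659 for hypoxia and 0.0951 for the last 2. DLL4 rose by 8.13 (SE 0.30), DLX2 by 6.79 (SE 0.26), RNF151 by 6.59 (SE 0.40) and the calcitonin gene CALCA by 6.51 (SE 0.39). PERM1 and TSSK2 had 0 reads in the controls and were at least 94.2-fold and 79.4-fold higher. INSM2, STPG3, FOXQ1, KLF2, MUC22 and TAC4 had 2 or 3 control reads, with ratios of 129-fold (KLF2; 42.9 to 635) to 219-fold (STPG3; 73.9 to 1070). DAZL fell by 5.52 (SE 0.43), PI15 by 4.60, APLN by 4.52, the water channel AQP4 by 4.39 and the cytokinesis regulator ARHGAP19 by 4.28 (SE 0.17), and EDNRB, INMT, IGFBP5, CD302 and SLC35A1 were among the largest decreases. IGIP had 3 treated reads and was 26.5-fold lower. The count at 500 µM was 203, 207 and 200 without its replicates 1, 2 and 3, and 790 with no filter on low counts, where 30.9% rather than 52.6% of the calls were increases. At 650 µM it was 3458 and 3040 without replicates 2 and 3.

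**Figure D2:**
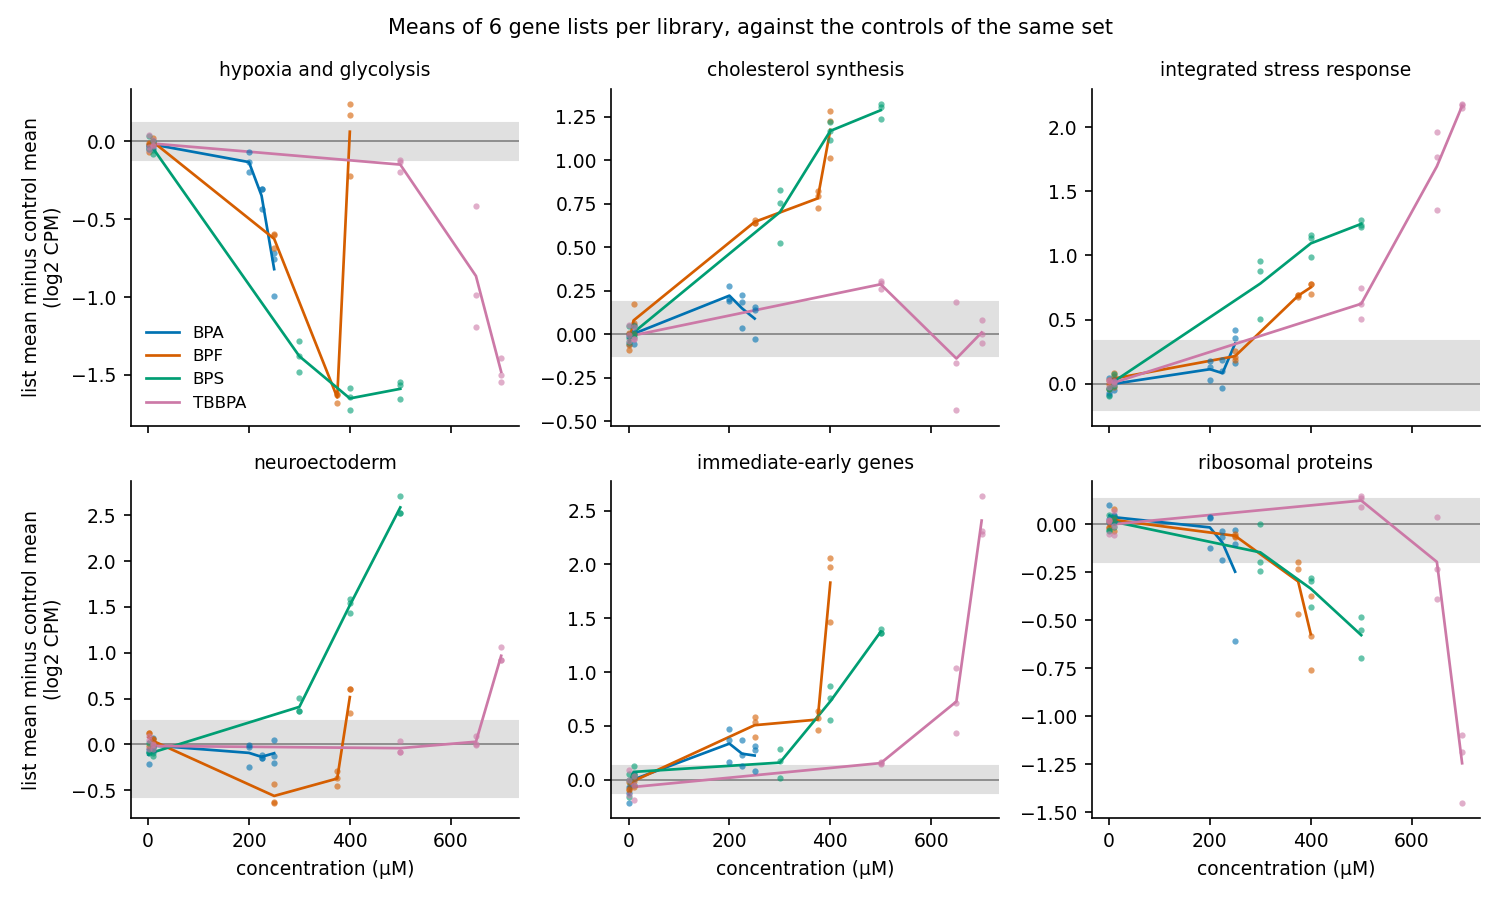
Mean log2 CPM of 6 gene lists minus the mean of the controls of the same set, against concentration in µM. Each point is a library, lines join the means of 3 libraries per compound, and the grey band is the range of the 7 high-set controls. The hypoxia and glycolysis mean is -1.59 at 500 µM BPS and 0.06 at 400 µM BPF, and the neuroectoderm mean is 2.59 at 500 µM BPS.

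The core pluripotency factors were followed at the highest concentration of each compound. SOX2 fell by 0.97 (SE 0.10) at 250 µM BPA, by 0.81 (SE 0.10) at 400 µM BPF and by 0.23 (SE 0.10) at 700 µM TBBPA, and was at -0.10 at 500 µM BPS (adjusted p 0.372). NANOG rose by 0.94 (SE 0.14) with BPA and by 0.61 (SE 0.14) with BPF, and fell by 0.55 (SE 0.15) with BPS and by 1.35 (SE 0.16) with TBBPA; the BPS change did not pass against the own-run control (-0.25). POU5F1, which has near-identical pseudogenes, was at -0.47 (adjusted p 0.011) with BPA, where its own-run value was -0.25 and did not pass, and at 0.31, -0.14 and -0.06 with the others. The estrogen receptor ESR1 had 12 reads in the controls, and rose at 700 µM TBBPA to 1.46 ± 0.0661 CPM from 0.0447 ± 0.0459 CPM (log2 4.70, SE 0.43). With BPF and BPS ESR1 was at 1.75 (adjusted p 0.0261) and 1.91 (adjusted p 0.00861), with an own-run value of 5.39 for BPS, and with BPA it had 3 treated reads. ESR2 rose by 1.52 (SE 0.35) with BPF and by 1.06 (SE 0.37) with TBBPA and fell by 1.42 (SE 0.54) with BPS. The orphan receptor ESRRG, a known binder of BPA, rose by 0.89 (SE 0.14) with BPA and by 0.57 (SE 0.15) with BPF and fell by 1.49 (SE 0.18) with TBBPA. Against the own-run control the rises of ESR1 and ESR2 with BPF, of ESRRG with BPA and BPF and of ESR2 with TBBPA did not pass. ESRRA passed with none of the 4. Of 25 pluripotency genes at 700 µM TBBPA 16 fell and 6 rose, a list not called by camera (adjusted p 0.0916).

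Another 11 lists were called at none of the 12 high concentrations. At 700 µM TBBPA, xenobiotic metabolism genes showed 6 rises and 6 falls of 18, apoptosis regulators 6 and 11 of 22, blood and endothelial markers 3 and 1 of 5, endoderm 4 and 2 of 11 and heat shock genes 5 and 11 of 19. Mesoderm showed 7 rises and 5 falls of 13, naive pluripotency 5 and 2 of 8, steroid and thyroid receptors 6 and 5 of 19, steroidogenesis 1 and 4 of 7, trophoblast and amnion markers 5 and 3 of 9, and WNT targets 9 and 4 of 16. Among lists called at lower concentrations only, autophagy and lysosome genes (13 rose, 1 fell), DNA methylation and chromatin genes (10 fell, 1 rose), mitochondrial stress genes (5 rose, 3 fell) and epithelial-mesenchymal genes (10 rose, 1 fell) were called at 650 µM TBBPA. Cholesterol efflux genes were called higher at 400 µM BPS (4 of 8 rose) and lower at 650 µM TBBPA (3 fell, 1 rose). Ribosome biogenesis and MYC targets were higher at 400 µM BPS (16 of 27 rose, 3 fell), and replicative histones, which share reads, at 200 µM BPA (2 of 23 rose). With an estimated correlation none of these was called; the adjusted p-values were 0.128, 0.1504, 0.128 and 0.128 for the first 4, 0.211 and 0.291 for cholesterol efflux, 0.259 for ribosome biogenesis and 0.732 for histones.

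Reads of the mitochondrial genome, a marker of RNA composition and quality, rose beside these gene groups. They made up 24.8% of gene reads in the 7 controls and 35.1%, 42.1%, 48.1% and 60.3% in the 3 libraries each of 250 µM BPA, 400 µM BPF, 500 µM BPS and 700 µM TBBPA. Almost all of this was mitochondrial ribosomal RNA, at 24.0% in controls and 34.0%, 41.2%, 47.2% and 59.2% in these groups. The mitochondrial messenger RNAs made up 0.843% in controls and 1.125%, 0.873%, 0.983% and 1.089%. The differences were 10.3, 17.3, 23.3 and 35.5 percentage points, each with p = 0.00833 in a two-sided exact permutation test, the smallest it can give, and 0.01 after adjustment over the 12 high concentrations. At 200 µM BPA and 500 µM TBBPA the differences were 2.97 points (exact p = 0.0917) and 3.56 points (exact p = 0.0583). In the low set the share was 0.463% in the controls. It was 0.708% at 10 µM TBBPA, with all 3 libraries above every control (exact p = 0.0119, the smallest its 84 splits can give), and 0.733% at 1 µM BPF and 0.564% at 1 µM BPS (exact p = 0.0238 each). No group passed after adjustment (0.0635 for these 3), and libraries of over 30% multimapped reads are among those of 10 µM TBBPA and 1 µM BPF. Multimapped reads averaged 15.3% in the high controls, 23.7% at 500 µM BPS and 32.5% at 700 µM TBBPA.

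**Figure D3:**
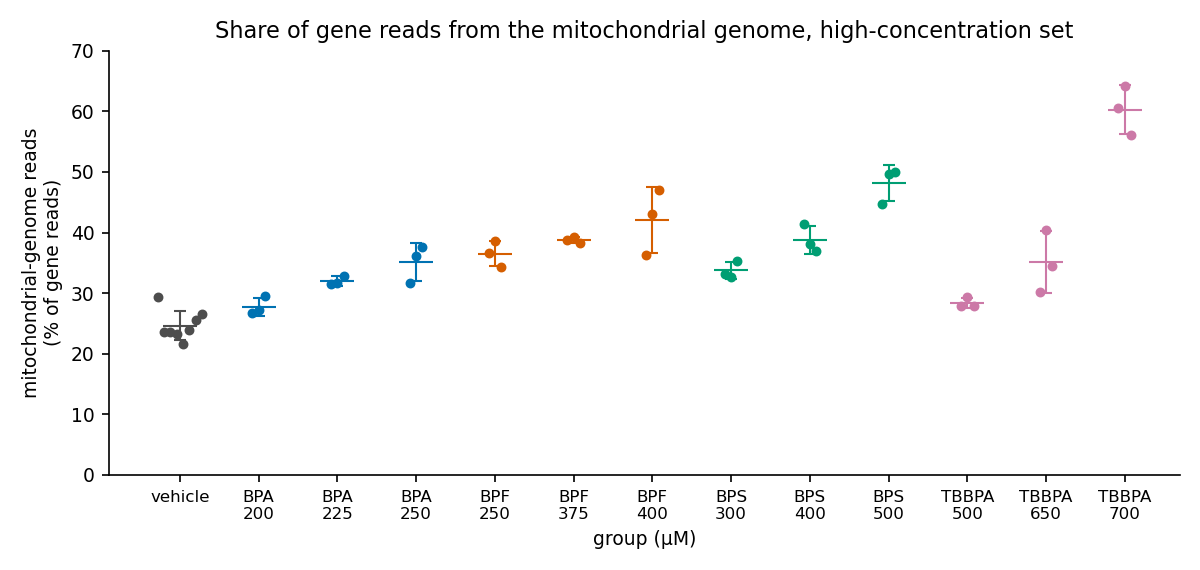
Share of gene reads from the mitochondrial genome, in percent, for each library of the high set, with the mean and SD of each group. Controls are at the left, as 8 separate libraries of which the text counts 2 as 1 sample, and the concentrations in µM follow by compound. The mean is 60.3% at 700 µM TBBPA.

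BPA and BPF, which differ in the bridge, were compared at 250 µM. TLR4 was higher with BPA, at 5.07 ± 0.725 CPM against 0.332 ± 0.182 CPM with BPF (log2 3.81, SE 0.35, adjusted p 1.10e-09), but did not pass relative to own-run controls (3.28, adjusted p 0.315). The direct contrast gave 5148 genes, 2481 of them higher with BPA. Relative to each compound's own-run control only 27 genes differed, 14 of them also in the direct contrast, and 87.9% of the 5148 had the same sign. GREB1L, ZEB2 and LGI1, at 5.52, 4.17 and 3.82 in the direct contrast, were then at 0.08, 0.11 and 0.12. LIX1 had 3 reads with BPF and was 26-fold higher with BPA (8.58 to 129), with an own-run log2 of 0.13. Lower with BPA were LRRC61, PXMP4, MAGEA4, ZNF736 and GJA4, at -4.10 to -2.50, none of which passed relative to the own-run controls. Of 26 cholesterol synthesis genes 20 were lower with BPA (mean -0.56, 95% interval -0.75 to -0.36; adjusted p = 0.438 with an estimated correlation), and the own-run difference was -0.39 (-0.79 to 0.00). Pluripotency genes were lower in 12 of 25 cases and higher in 1 (mean -0.52), with an own-run difference of -0.14, and neuroectoderm genes differed in sign between the direct contrast (0.47) and the own-run difference (-0.25). The count was 2932 without BPA replicate 1 and 3197 without BPF replicate 2.

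BPF and BPS at 400 µM differed most in hypoxia and glycolysis genes, of which 30 of 33 were higher with BPF and 0 lower (32 adjusted over the list alone). The mean difference was 1.71 (95% interval 1.48 to 1.94; own-run 1.66, 1.17 to 2.15), with adjusted p = 0.00374 with an estimated correlation. BHLHE40, a hypoxia-induced repressor, was at 264 ± 95.2 CPM with BPF and 4.28 ± 0.819 CPM with BPS (log2 5.94, SE 0.31, adjusted p 1.34e-16; own-run 6.01), and ANKRD37 differed by 5.76 (SE 0.36). DUOX2 and KLRD1 had 0 reads with BPS and were at least 114-fold and 26.2-fold higher with BPF, and NOG was higher by 7.22 (SE 0.39). Immediate-early genes were higher with BPF in 21 of 30 cases (interval of the mean 0.85 to 1.36; own-run mean 1.07; adjusted p = 0.117 with an estimated correlation), and cytoskeletal genes in 18 of 26 (mean 0.67; p = 0.135). Neuroectoderm genes were lower with BPF in 18 of 25 cases and higher in 1 (interval of the mean -1.30 to -0.70; own-run -0.99; p = 0.117), among them PAX6 at -2.43 (SE 0.41; own-run -2.32) and LHX2 at -2.27 (SE 0.30; own-run -8.58, SE 1.38). LHX2 had 47 reads over all controls, so the size of its own-run value rests on few reads and is not reliable. RSPO3, LIX1 and DPPA3 were lower by 3.35, 2.55 and 2.44 in the direct contrast. Of these 3 only LIX1 passed relative to own-run controls (RSPO3 and DPPA3 had adjusted p = 0.153 and 0.319). In total 7652 genes differed, 3952 of them higher with BPF, and 1219 relative to own-run controls, with 97.8% of the 7652 keeping their sign.

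BPS and TBBPA at 500 µM differed in 11958 genes, 5825 of them higher with BPS. Relative to own-run controls 5855 differed, and 97.1% of the 11958 had the same sign. Neuroectoderm genes were higher with BPS in 22 of 25 cases and lower in 0 (mean 2.63, 95% interval 2.33 to 2.93; own-run 2.60; adjusted p = 0.00348 with an estimated correlation). LHX2 was at 18.5 ± 1.65 CPM with BPS and 0.259 ± 0.111 CPM with TBBPA (log2 6.09, SE 0.34, own-run 11.98). As above, the size of this own-run value is not reliable. DLL4 was higher by 6.06 (SE 0.41). Neural crest genes (8 higher, 1 lower; adjusted p = 0.0312), imprinted genes (10 higher, 1 lower; p = 0.0108) and TGF-beta, NODAL and BMP targets (19 higher, 2 lower; p = 0.0124) were also called with an estimated correlation, the neural crest list not relative to own-run controls (p = 0.0781). ZBTB16, INSM2 and STOML3 had 1 read with TBBPA and were 182-fold (32.2 to 7260), 111-fold and 99.4-fold higher with BPS, and none of the 3 passed relative to own-run controls. Hypoxia and glycolysis genes were lower with BPS in 28 cases and higher in 2 (mean -1.44; own-run -1.30; p = 0.0742), and mitosis genes lower in 28 and higher in 1 (mean -0.88; p = 0.167). Cholesterol synthesis genes were higher in 21 cases and lower in 1 (mean 1.00; own-run 1.09; p = 0.167). CD300A was 219-fold and RDH8 89-fold lower with BPS, and APLN, ANKRD33 and APOBEC3B were lower by 5.43, 4.98 and 4.95.

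Between the lowest and highest concentrations of BPA, 22 hypoxia and glycolysis genes fell further (27 adjusted over the list alone; mean -0.69, 95% interval -0.92 to -0.46; adjusted p = 0.0161 with an estimated correlation). The lactate exporter SLC16A3 fell by 1.65 (SE 0.36), APLN by 1.63 and SYNDIG1L by 1.64, and WNT10B and SPAG4 fell by 1.69 and 1.57. MT-ATP8 of the mitochondrial genome, the cystine transporter SLC7A11, ULBP1 and FAM151B rose by 1.64, 1.06, 1.27 and 1.14, and MT-CYB rose as well. In total 675 genes differed, and the count was 43 without replicate 1 of 200 µM, 41.6% of 675 without its replicate 2, and 65 and 350 without replicates 1 and 2 of 250 µM. From 300 to 500 µM BPS 10909 genes differed: 23 of 25 neuroectoderm genes rose (mean 2.18; adjusted p = 0.00183), with VAX1 at 4.68 (SE 0.56), and NANOG fell by 1.84 (SE 0.18). Imprinted and neural crest genes were also called with an estimated correlation (adjusted p = 0.00583 and 0.0306). ZBTB16, PAX8 and CNTN6 rose by 4.52, 4.19 and 4.13, STOML3 was 39.3-fold higher from 2 reads, and MEIOB, VWC2, DPPA2 and GABRP fell by 3.50, 3.40, 3.19 and 3.18, with OR52A1 34.2-fold lower.

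From 500 to 700 µM TBBPA 14623 genes differed. Oxidative phosphorylation genes fell in 40 of 42 cases (mean -1.57), and 23 of 30 immediate-early genes rose while 4 fell (mean 2.25). These lists had adjusted p = 0.516 and 0.305 with an estimated correlation, and none was called with it. DLL4 rose by 7.39 (SE 0.40), KLF2 and MUC22 were at least 44.4-fold and 32.9-fold higher, INSM2 and GATA2 were 199-fold and 173-fold higher from 1 read, and PI15, APLN, AQP4 and ARHGAP19 fell by 4.78, 4.72, 4.71 and 4.41. IGIP was 26.5-fold lower. From 250 to 400 µM BPF 9048 genes differed, but 339 relative to own-run controls, and 90.5% of the 9048 had the same sign. EGR1, BHLHE40 and MXD1 rose by 4.91, 4.77 and 4.76 (own-run 3.55, 3.98 and 4.47), whereas GREB1L and LIX1, at 6.27 and 4.89, were at 0.68 and 0.83 with own-run controls. KCNJ2 fell by 2.71 (own-run 1.63 lower). MAGEA4, ASTE1, TRDN and LRRC61, at -3.37 to -2.71, did not pass relative to own-run controls. There TRDN and LRRC61 had the other sign, at 0.25 and 0.23. Immediate-early genes rose in 23 of 30 cases (mean 1.32; own-run 1.41; adjusted p = 0.139 with an estimated correlation).

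At 1 and 10 µM, VIM was called lower in 6 of the 8 comparisons with controls, COL6A1 in 4 and AHNAK in 2. In each of these 8 comparisons, splits of the libraries that ignore the run gave as many genes too often to exclude chance. For 10 µM BPA, 10 µM BPF and both BPS concentrations, whose libraries the run pairs, splits that keep the pairs are too few to tell. With only the groups compared in the fit, edgeR called 0 genes in each of the 7 comparisons that had calls. BPA at 1 µM changed 14 of 17876 genes, 3 up and 11 down. The count was 102 with DESeq2, 139 with no filter on low counts and 199 with only the controls of its runs. With the run as a block it was larger than each of these, as given below. These libraries share their runs with controls, but their deviations did not correlate with r above 0.1 in every run. APELA, a peptide hormone of pluripotent cells, rose by 0.79 (SE 0.13; 27.4 ± 4.35 against 15.8 CPM), SACM1L rose by 0.20, and the protease inhibitor SPINT1, ATCAY, RPAP1 and ELOA fell by 0.41, 0.38, 0.31 and 0.29. BPA at 10 µM changed 6, among them these: the potassium channel KCNJ2 rose by 0.44 (SE 0.07), and the collagen COL6A1, AHNAK, vimentin (VIM) and LAMA1 fell by 0.36, 0.36, 0.30 and 0.21. LAMA1 was chosen after its values were seen. VIM was at 107 ± 2.22 CPM against 131 CPM (adjusted p 0.00215). At 10 µM 105 genes changed with the run as a block, 24 with DESeq2 and 41 with no filter. At 1 µM the count was 0, 35 and 4 without BPA replicates 1, 2 and 3 and 26, 7, 34, 8 and 633 without control replicates 1, 3, 5, 9 and 11. At 10 µM it was 0, 2 and 3 without its replicates and 2, 15 and 29 without control replicates 3, 5 and 11.

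BPF at 1 µM changed 3 genes: VIM fell by 0.26 (SE 0.05), the transferrin receptor TFRC by 0.24 (SE 0.04) and EIF4HP1, a pseudogene chosen after its values were seen, by 0.92. At 10 µM it changed 2: VIM fell by 0.28 (SE 0.05) and KCNJ2 rose by 0.43 (SE 0.07), and 28 genes changed with the run as a block. DESeq2 gave 8 at 1 µM, and no filter gave 19 and 9. At 1 µM the run as a block also gave more than 3 genes, as given below. The count at 1 µM was 0 without each of its replicates or control replicate 9 and 7 without control replicate 11; at 10 µM it was 1, 0 and 1 without its replicates and 5 and 7 without control replicates 1 and 11. TBBPA at 1 µM changed 4 genes (22 with DESeq2, 38 with no filter, and more than 4 with the run as a block, given below). Among the 4, the histone H2BC7 rose by 0.26, and VIM and the RNA acetyltransferase NAT10 fell by 0.25 and 0.25. Without TBBPA replicates 1, 2 and 3 the count was 0, 2 and 1, it was 0 without control replicates 1, 3, 7 or 9, and it was 60 without control replicate 11. At 10 µM edgeR called 0 genes, with 988 at an unadjusted p under 0.05, and DESeq2 called 1; without control replicate 11 edgeR called 3.

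BPS at 1 µM changed 31 genes, 10 up and 21 down, against 65 with the run as a block, 95 with DESeq2, 131 with no filter and 5 with only the controls of its runs. JAKMIP2, a neuronal microtubule-associated gene, rose by 0.34 (SE 0.06), PLA2G2A by 0.43, CA11 by 0.26 and the protocadherin PCDH11X by 0.26. The myelin gene PMP22, the laminin LAMC3, CR2 and the collagen COL9A3 fell by 0.72 (SE 0.13), 0.52, 0.50 and 0.44. At 10 µM 15 genes changed, 7 up and 8 down, against 52 with the block, 32 with DESeq2, 49 with no filter and 8 with only the controls of its runs: COL8A1 rose by 0.87 (SE 0.15), LPAR6 by 0.45, JAKMIP2 by 0.32 and PCDH11X by 0.27, and the cardiac actin ACTC1, AHNAK, NAT10 and the glypican GPC3 fell by 0.43, 0.36, 0.29 and 0.25. Without the replicates of 1 µM in turn the count was 9, 12 and 2, and without control replicates 1, 3, 7 and 11 it was 18, 17, 14 and 542. Without those of 10 µM it was 7, 0 and 2, and without control replicates 7 and 11 it was 9 and 74. POU5F1, NANOG, SOX2, ESR2, ESRRA and ESRRG passed at none of the 8 low concentrations, and ESR1 did not pass the expression filter.

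Of the 45 lists, 4 to 6 were called at each low concentration with the preset correlation, and none with an estimated one. Genes of ribosome biogenesis were lower at 10 µM BPA (mean -0.07, 95% interval -0.11 to -0.03; 5 lower adjusted over the list alone and 0 over all genes; adjusted p = 0.102 with an estimated correlation). Metallothionein-list genes were at -0.26 at 1 µM BPS (4 lower adjusted over the list alone; adjusted p = 0.203) and 0.16 at 10 µM TBBPA (2 higher; p = 0.248). Mitochondrial genome genes were at 0.72 at 10 µM TBBPA (0.23 to 1.21; 8 higher adjusted over the list alone; adjusted p = 0.0525). Replicates 2 and 3 of 10 µM TBBPA had 31.2% and 47.6% multimapped reads and 7.45% and 15.9% of gene reads on the other strand, so its values mix the compound with library quality. With the run as a block, ribosome biogenesis genes at 1 and 10 µM BPS and oxidative stress genes at 10 µM BPF were called with an estimated correlation too (adjusted p 0.00606, 0.00274 and 0.0395). Between the compounds, 2 genes differed at 1 µM and 2 at 10 µM, the pseudogenes EIF4HP1 and NAP1L1P1 both times, which were chosen after their values were seen. BPA and BPF shared 3 runs and BPS and TBBPA another 3, so these 2 groups of compounds were also set against the controls of their runs, with the run as a block, which gave 1 and 7 genes. EIF4HP1 passed there (adjusted p = 0.0133 and 0.0358) and NAP1L1P1 did not (0.662 and 0.579). Both genes were lower with BPA and BPF than with BPS and TBBPA, as these runs divide the compounds. A run difference therefore stays open for NAP1L1P1. For EIF4HP1 a run difference in the treated wells alone stays open, since the block removes only what the controls share. Metallothionein-list genes were lower with BPS than TBBPA at 10 µM (mean -0.37, -0.55 to -0.19; adjusted p = 0.00169 with an estimated correlation, and 0.00517 with the run as a block), with 6 genes passing adjusted over the list alone and 0 over all genes. Between BPA and BPS at 1 µM, which lie in different runs, the mean was 0.33 (p = 0.0195) directly and 0.23 (-0.01 to 0.48; p = 0.405) with the run as a block, so a run difference is not excluded there.

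BPA had the lowest median benchmark concentration, 104.5 µM (95% interval 84.0 to 131.6, 1042 genes), followed by BPF at 183.2 µM (127.6 to 228.9, 3549 genes), BPS at 225.5 µM (199.2 to 253.4, 4963 genes) and TBBPA at 615.4 µM (597.8 to 617.7, 8284 genes). Relative to BPA the median was 1.75-fold higher for BPF (1.09 to 2.24), 2.16-fold for BPS (1.61 to 2.77) and 5.89-fold for TBBPA (4.63 to 7.18). BPS exceeded BPF 1.23-fold (1.02 to 1.62). By list, hypoxia and glycolysis genes had medians of 189.6 µM for BPA, 214.5 µM for BPF, 90.5 µM for BPS and 557.2 µM for TBBPA. Integrated stress response genes had 224.7 µM for BPF, 105.7 µM for BPS and 399.1 µM for TBBPA, and cytoskeletal genes 54.0, 31.1, 125.4 and 608.5 µM in the order BPA, BPF, BPS and TBBPA. Of the gene values, 81.5% for BPA, 60.8% for BPF, 67.7% for BPS and 7.1% for TBBPA lay between 10 µM and the lowest high concentration, where no library was made, so they rest on the curve alone. The sets of genes differ between compounds, and the highest concentrations do as well. The benchmarks used the mean of all controls of a set, and no benchmark was made against own-run controls. In the high set the compounds lie in different runs, so differences between runs may be part of the medians and their ratios.

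**Figure D4:**
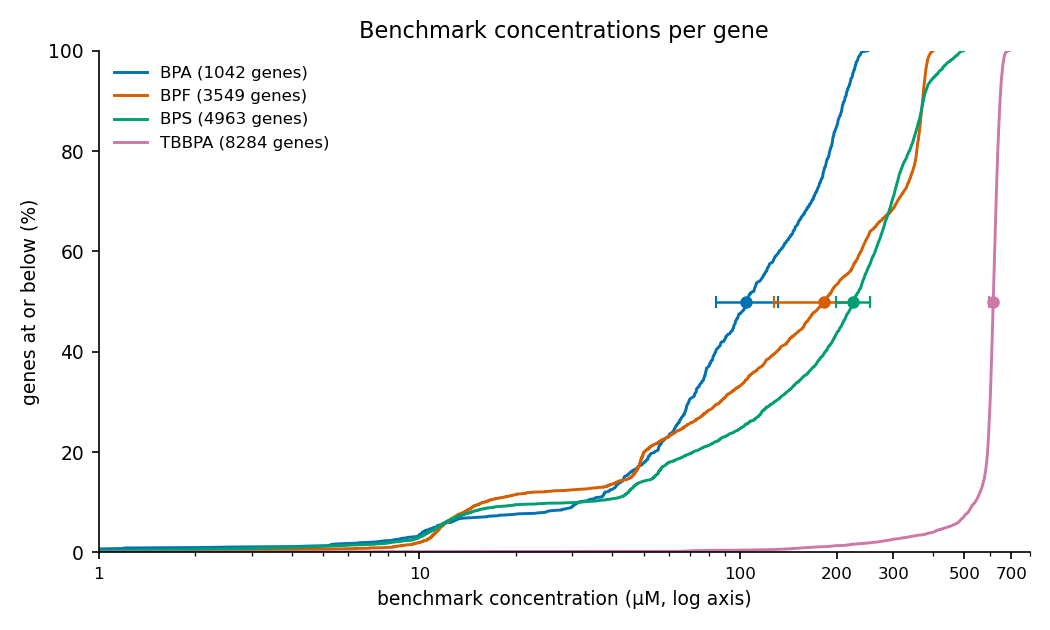
Cumulative percentage of genes against their benchmark concentration in µM on a log axis, 1 line per compound, with the median and its 95% interval as a point and bar. The medians are 104.5 µM for BPA, 183.2 µM for BPF, 225.5 µM for BPS and 615.4 µM for TBBPA, and no library was made between 10 and 200 µM.

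At the highest concentrations the fold changes of BPS and TBBPA were most alike across genes, with Pearson r of 0.71, 4697 genes higher and 5222 lower with both, and 934 called in opposite directions. LHX2, DLX2, DLL4, FOSB and ASNS rose and LDHA and APLN fell with both. BPF and BPS had r of 0.58 (3206 and 3595 shared, 744 opposite) and BPF and TBBPA 0.50 (3301 and 3834, 1306 opposite). BPA had r of 0.33 with BPF (1116 and 1200, 1065 opposite), 0.32 with BPS (1114 and 1529, 1453 opposite) and 0.13 with TBBPA (921 and 1364, 2468 opposite). Independent lists would share 2278 and 2749 for BPS and TBBPA, 1575 and 1731 for BPF and BPS, 1876 and 2096 for BPF and TBBPA, 694 and 881 for BPA and BPF, 843 and 1156 for BPA and BPS, and 1003 and 1399 for BPA and TBBPA. For BPA and TBBPA the shared counts lie below these, but with own-run controls the shared counts, 506 of them lower, exceed what independent lists would share in both directions. The 4 compounds share controls, and 100 simulations of unchanged groups against them gave a median r of 0.30 and a covariance of 0.024. The observed covariances exceeded it by 1.285 for BPS and TBBPA, 0.508 for BPF and BPS, 0.596 for BPF and TBBPA, 0.13 for BPA and BPF, 0.199 for BPA and BPS and 0.103 for BPA and TBBPA. With the controls split between the compounds, r was 0.69, 0.54, 0.47, 0.27, 0.28 and 0.12, and with own-run controls 0.62, 0.50, 0.48, 0.42, 0.34 and 0.32, each in the same order. These correlations are across genes, which are not independent replicates, over 6 pairs.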

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

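Some tests were chosen only after the result was seen: the test of mitochondrial ribosomal RNA, the 3 tests of hypoxia and glycolysis genes at 400 µM BPF, the comparison of 1 with 10 µM, the splits of 200 and 10 µM BPA, and the splits that keep the runs. Of 104 control measures tested for a single value far from the rest of its group, 8 had one, and about 1 in 20 groups would give one by chance. Replicate 1 of the low-set controls had 0.388% of gene reads from the mitochondrial genome (the others 0.464 to 0.503%), a mean of 5.94 for the 13 mitochondrial messenger RNAs (6.31 to 6.48, log2 CPM) and 17282 genes with at least 10 reads. Replicate 11 had the lowest means of 4 lists: blood and endothelium at 0.02 (0.22 to 0.33), fat oxidation at 4.61 (4.71 to 4.75), immediate-early genes at 3.61 (3.82 to 3.92) and steroid and thyroid receptors at 2.87 (2.98 to 3.04). In the high set, control replicate 2 had fat oxidation at 4.38 (4.16 to 4.25).

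For 6 lists, 2 compounds at 1 concentration moved in opposite directions, and each movement and the difference passed in a limma test of the list mean. At 400 µM, BPF exceeded BPS by 0.28 in genes of DNA methylation and chromatin and by 0.51 in retinoic acid targets (own-run 0.37, 95% interval 0.09 to 0.64, and 0.49, 0.03 to 0.96). At 500 µM, BPS exceeded TBBPA by 0.66 in cholesterol efflux, 0.90 in endoderm and 1.08 in TGF-beta, Nodal and BMP targets (own-run 0.78, 0.78 and 1.14). The p53 targets differed by -0.59 (own-run -0.31, -0.59 to -0.03). By camera with an estimated correlation, only the difference in TGF-beta, Nodal and BMP targets passed (adjusted p = 0.0124, and 0.335 to 0.733 for the other 5). Reads on the other strand, which no comparison used, were 7.32% of gene reads in replicate 1 of 225 µM BPA, the 1 high-set library above the highest control (4.03%). Among low-set libraries 10 lay above the highest control (4.77%), with 22.4% in replicate 2 of 1 µM BPF.

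The share of gene reads from the mitochondrial genome was higher at high concentrations. Nearly all of the rise was ribosomal RNA, from 24.0% in controls to 59.2% at 700 µM TBBPA, while the messenger RNAs went from 0.843% (SD 0.168) to 1.089% (SD 0.233). Depth does not account for it: of 31 treated libraries within the depth range of the controls, 28 had a share above the highest control (29.3%). Less complete removal of this ribosomal RNA as the only change is argued against for BPA and TBBPA, where the lower 95% bound of the list mean of the 13 messenger RNAs, relative to other genes, was at least 0.17 with all and with own-run controls. As a source of most of the rise it stays open for all 4 compounds, and as the only change for BPF and BPS (lowest bound -0.19, for BPS with own-run controls), and a change within the cells was not tested.

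Hypoxia and glycolysis genes were lower at 375 µM BPF but not at 400 µM. The tables argue against a shift that all libraries of a run share. The 400 µM mean lay above that at 375 µM by 1.59 with each set against its own control (95% interval 1.12 to 2.07). A run difference in the treated wells alone stays open, as each concentration lies in 1 run with 1 control. The tables argue against a single library, since the lowest library at 400 µM was above the highest at 375 µM by 1.4. A candidate explanation is a recent rise of hypoxia-induced genes over a lasting fall of glycolysis enzymes: 9 of 14 enzymes were lower and 1 higher at 400 µM, while 9 of 19 other members were higher and 5 lower. It stays open, because there is 1 time point.

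At low concentrations 4 genes (among them VIM 6 times, COL6A1 4 and NAT10 3) were called in 3 or more of the 8 comparisons, lower each time. The tables argue against independent chance values of the shared controls, since 100 simulations of unchanged groups gave at most 0 such genes. As for a single control library, at least 2 of the 4 were still called this often whichever control was left out (the bound set for this test was 2, so it is only just met), and the number of such genes was 2, 2, 6 and 61 without control replicates 3, 9, 5 and 11. A response that grows from 1 to 10 µM stays open: 4 of 16 pairs of gene and compound had the larger change at 10 µM, 0 of them by more than 2 SE, and 1 pair had the smaller change at 10 µM by more than 2 SE. A difference in handling between vehicle and treated wells stays open, as the simulated libraries were independent of each other.

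The libraries of each comparison were also split in other ways, with the real split counted. For 200, 225 and 250 µM BPA, 1 of 100 splits gave as many genes, the real one (1940, 4650 and 6086, against at most 1315, 2037 and 3334 in another). The same 1 of 100 held for BPF (6317, 9536 and 10116, against 3572, 4508 and 6814), BPS (6996, 10470 and 12782, against 1936, 3767 and 6050) and 650 and 700 µM TBBPA (5636 and 15355, against 3954 and 9786), so chance is excluded for these splits, which ignore the run. For 500 µM TBBPA 8 of 100 splits gave as many as the real 460, so chance is not excluded. The highest other, 876, set control replicates 4, 5 and 6 apart, and 271 genes were called with only the own-run control in the fit. Controls set apart from other libraries gave up to 3572 genes, and the controls of 2 runs differed from the other 5 in 2404, more than the 1940 at 200 µM BPA, so a run difference is not excluded by these splits.

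Splits that ignore the run do not exclude chance for any of the 8 low-set comparisons with controls. Of 84 splits, 10 and 5 gave as many genes as the real 14 and 6 at 1 and 10 µM BPA (highest other 2527 and 57), and 7 and 11 as many as the 3 and 2 with BPF (116 and 498). With BPS, 9 and 6 gave as many as 31 and 15 (2264 and 411), and with TBBPA, 11 as many as 4 at 1 µM (1358) and all 84 as many as 0 at 10 µM (2035). The highest split placed control replicate 11 among treated libraries for 1 µM BPA, 10 µM BPF and each BPS and TBBPA concentration, which points to a structure of the samples in which this control stands apart. The counts with the run as a block are given below. Between the 4 compounds, 1 of 100 splits gave as many as the 2 genes at 1 µM and at 10 µM, the real one (highest other 1 and 0), so chance is excluded for these splits, which ignore the run. Both genes divide along the runs that the compounds share, and a run difference stays open for NAP1L1P1, as above. For 10 µM BPA, 10 µM BPF and 1 and 10 µM BPS, where the run pairs the libraries, the splits that part as many pairs number 8, too few for a share under 0.05. The real counts and highest others were 6 and 3, 2 and 1, 31 and 1, and 15 and 1. With the run as a block these are 4 splits up to mirrors, again too few, with 105, 28, 65 and 52 genes and 0 in every other.

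The 7 comparisons of 3 with 3 libraries have 10 splits each, too few for a share under 0.05. The real values and highest others were 5148 and 0 for BPA and BPF, 7652 and 0 for BPF and BPS, and 11958 and 0 for BPS and TBBPA. Between concentrations they were 675 and 0 for BPA, 9048 and 1 for BPF, 10909 and 0 for BPS and 14623 and 0 for TBBPA. In each, 1 of 10 splits gave as many genes, the real one.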

How the results depend on the processing

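The alternatives added after the first results were seen are the mitochondrial genome left out, TBBPA at 700 µM left out, 3 multimapped libraries left out, each low-set control left out, own-run controls for the similarity, own-run differences for the contrasts between groups, the run as a block for the metallothionein list between compounds, and split or own-run controls for the genes called at all 12 high concentrations. Each group has 3 libraries, and most runs of the high set have 1 control, so run and compound can be told apart only through these controls; the cause of the differences between controls was not tested. The genes named by the rule had 19228 values under the alternatives, not counting own-run differences between groups. Of these values, 18651 had the same outcome of the test, 554 lost their call, 23 gained one and 0 called values changed sign. In a wider set that adds list members, 5 of 2026 called values had the other sign against the own-run control. AFP at 200 µM BPA was among them (-1.49 and 0.42), and 0 of the 5 passed there. As differences between own-run differences, 27 of 689 had the other sign, some of them of genes named by the rule. Between 400 and 250 µM BPF they included TRDN (-2.86 and 0.25), LRRC61 (-2.71 and 0.23), NANOG (-0.55 and 0.43) and ESR2 (1.28 and -0.86). ETS1 in that contrast passed with the other sign (-0.56 and 0.97). Leaving out the mitochondrial genome or TBBPA at 700 µM, or scaling by relative log expression, moved 0 counts by more than 1.5 times. Relative log expression also takes most genes as unchanged, so it does not test the scaling where most genes changed.

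With only the own-run control fitted, the counts for BPA were 621, 832 and 1417, for BPF 629, 3550 and 4197, for BPS 3661 and 5952 at 300 and 400 µM, and for TBBPA 271 and 2207 at 500 and 650 µM. With only controls of the same title form the count was 3104 at 250 µM BPF. With only the groups compared in the fit the counts were 1029 and 3879 at 200 and 250 µM BPA, 191 and 2987 at 500 and 650 µM TBBPA and 90 between the BPA concentrations. In the low set that choice gave 0 genes in edgeR in each of the 7 comparisons with calls, and 5 and 13 between the compounds at 1 and 10 µM. As differences between own-run differences, the counts were 27 for BPA and BPF, 1219 for BPF and BPS, 5855 for BPS and TBBPA and 339 for 400 and 250 µM BPF.

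With no filter on low counts, 790 genes changed at 500 µM TBBPA and 1035 between the BPA concentrations. In the low set, without the filter, 139 and 41 changed at 1 and 10 µM BPA, 19 and 9 with BPF, 131 and 49 with BPS, and 38 and 4 with TBBPA, and 6 and 7 differed between the compounds. DESeq2 gave 1014 between the BPA concentrations, 102 and 24 at 1 and 10 µM BPA, 8 at 1 µM BPF, 95 and 32 with BPS, 22 and 1 with TBBPA, and 4 between the compounds at 10 µM. With the 2 libraries of each control pair kept apart, 86 and 10 changed with BPA, 83 and 31 with BPS, 16 at 1 µM TBBPA, and 0 between the compounds at either concentration in edgeR. With only the controls of the compound's title runs, 199 changed at 1 µM BPA, 5 and 8 with BPS and 2 at 1 µM TBBPA. With the run as a block the counts were 682 and 105 with BPA, 14 and 28 with BPF, 65 and 52 with BPS, 26 and 2 with TBBPA, and 1 and 7 between the compounds. Without the 3 libraries of over 30% multimapped reads the counts were 0 at 1 µM BPF, 20 at 1 µM BPS, 0 at 1 µM TBBPA and 1 between the compounds at 10 µM. With an estimated correlation 48 list calls were made, and in the 4 comparisons of paired libraries the block gave 35 list calls in place of 19.

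Leaving out 1 library at a time, the lowest and highest counts were 1128 and 2123 at 200 µM BPA (without its replicate 3; without control replicate 7), 2241 and 4995 at 225 µM BPA (replicate 3; control 1), 200 and 548 at 500 µM TBBPA (replicate 3; control 7) and 3040 and 6714 at 650 µM TBBPA (replicates 3 and 1). They were 2932 and 5159 for BPA and BPF (BPA replicates 1 and 3) and 43 and 891 between the BPA concentrations (replicate 1 of 200 µM, replicate 3 of 250 µM). In the low set they were 0 and 633 at 1 µM BPA, 0 and 29 at 10 µM, 0 and 7 at each BPF concentration, 2 and 542 at 1 µM BPS, 0 and 74 at 10 µM, 0 and 60 at 1 µM TBBPA and 0 and 3 at 10 µM, each highest without control replicate 11. Between the compounds at 10 µM they were 1 and 3 (BPA replicate 1, BPF replicate 3).

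The benchmark medians of BPA, BPF, BPS and TBBPA were 132.2, 227.0, 251.7 and 620.1 µM for a 1.5-fold response and 174.05, 257.51, 291.98 and 641.9 µM for 2 SD. With the high set alone BPF, BPS and TBBPA had 221.2, 244.6 and 622.3 µM, and with linear and power curves alone BPS had 190.7 µM. Without replicate 3 or 1 of 300 µM the BPS median was 205.6 and 234.6 µM. The r between compounds with own-run controls was 0.42 for BPA and BPF, 0.32 for BPA and TBBPA, 0.50 for BPF and BPS and 0.62 for BPS and TBBPA. With split controls it was 0.28 for BPA and BPS and 0.69 for BPS and TBBPA. Leaving out 1 library, r ranged from 0.23 to 0.35 for BPA and BPF, 0.28 to 0.32 for BPA and BPS, 0.53 to 0.58 for BPF and BPS, 0.46 to 0.50 for BPF and TBBPA and 0.69 to 0.71 for BPS and TBBPA.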

Other observations

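The comparison of calls across all concentrations and the comparison of the low set with the high set were chosen only after the results were seen. Some genes moved in 1 direction at every one of the 12 high concentrations, 28 of them higher and 49 lower. The 12 comparisons share the same 7 controls, so this number may rest partly on them. In 100 simulations of 12 unchanged groups the number was at most 0, which leaves out the effects and so does not measure the part of the controls. With the controls split between BPA with BPF and BPS with TBBPA, the median over 20 splits was 20 higher and 40 lower, and with own-run controls 17 and 36 were called. GBX2, a homeobox gene of the early hindbrain border, rose by 1.31 to 3.33, and HEY1 and HEY2, repressors downstream of Notch, rose by at least 1.06 and 0.53. SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose between 0.66 and 1.06 whatever the compound. The neuroendocrine granule protein CHGA rose by up to 2.18 and the lysophosphatidic acid receptor LPAR6 by 1.06 to 2.94. Among the lower genes, DAZL, a germ-cell RNA-binding protein, was at -1.38 at 500 µM TBBPA and -5.52 at 700 µM. The ion-channel gene TMC1 lay between -4.97 and -2.91, the cation channel TRPC6 between -3.64 and -1.63, and APELA, a hormone of pluripotent cells, between -3.68 and -1.60.

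Other genes had differing values between concentrations or compounds, without a test of the difference given here. SOX21 was at -3.08 at 250 µM BPA, at -1.98 at 300 µM BPS and at 1.14 at 500 µM BPS. DUSP6 was highest at the lower concentrations of BPS and TBBPA: 1.42, 0.88 and 0.61 over the 3 BPS concentrations and 1.56, 1.65 and -0.11 over those of TBBPA. With BPF, NODAL and LEFTY1 were at 2.62 and 3.44 at 375 µM and at 0.34 and 0.41 at 400 µM. These concentrations lie in different runs, LEFTY1 was at 2.25 at 375 µM against its own-run control, and the difference was not tested.

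Of the 61 pairs of gene and compound called at 1 or 10 µM, 27 passed in the same direction at the highest concentration of that compound, 17 in the opposite direction and 17 did not pass. About 17.2 would pass in the same direction if the 2 sets were independent, and the sets have different controls. VIM, the intermediate filament of mesenchymal cells, fell at low concentrations and by 1.49, 1.46, 0.48 and 0.64 at the highest concentrations of BPA, BPF, BPS and TBBPA. COL6A1 fell by 0.96 at 250 µM BPA, and JAKMIP2 and COL8A1 rose at 500 µM BPS, JAKMIP2 by 0.53. APELA and PLA2G2A, which rose at 1 µM, were at -2.31 at 250 µM BPA and -3.88 at 500 µM BPS. The difference between 27 and 17.2 was not tested, since the called genes are not independent of each other.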
